A study of Mus musculus with 12 samples.

How the data were processed

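RNA was sequenced from purified dendritic cells of wild-type and Ythdf1-/- labelled mice, alone and after overnight culture with necrotic B16-OVA melanoma cells, with a stranded poly(A) library kit per the labels' protocols. The series holds 12 samples, of which 8 RNA-seq libraries in 4 groups of 2 had a column in the table used here. The 4 immunoprecipitation samples had none and were not analysed here. Groups and replicate numbers came from the sample titles. Nothing in the labels says that the 2 libraries of a group came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

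The deposited log2 values were read as made by the authors from read counts per Entrez gene with the regularized logarithm of DESeq2, which scales between libraries. This reading is an inference from the name of the table and from the submitters' processing notes, which name that tool. The notes also name STAR, deepTools and the mouse build mm9, with no versions. The counting tool, its strand setting, the gene annotation and the filter on genes are not given in the sources used here. A regularized logarithm pulls genes with few reads towards their mean, so their changes are understated. With no counts, the depth per library is unknown and no counting error could be given. Values lay between 3.24 and 17.88, with medians between 8.53 and 8.55. Near-identical genes (the Stfa and Cstdc cluster, Ly6c1 and Ly6c2, Ifit3 and Ifit3b, Hspa1a and Hspa1b, Lyz1 and Lyz2, the Ear genes) and overlapping or antisense genes are uncertain, since the counting could have split or shared their reads.

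Identifiers were matched to symbols in the GRCm38.p6 annotation, where 11744 had a symbol and 42 had none. This assembly differs from the build named by the submitters, so it served for names and for which genes neighbour each other, and no coordinate is given. Transcript GC content and length came from GRCm38 transcripts for 11486 of the genes tested (97.5%).

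Genes whose largest group mean was at least 4 were tested, which removed 1 gene and left 11785. The test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) on group means of all 8 libraries in 1 fit, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 4 residual degrees of freedom and 9.33 prior degrees of freedom. Adjusted p-values of single genes are from this fit. The contrasts were lysate against none in each genotype, KO-labelled against wild type in each treatment, the difference of the lysate effects, and the averages over genotype and over treatment. Figures were drawn with Python 3.11.15.

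Gene lists were fixed before the data were examined. They covered cathepsins, other lysosome genes, MHC class I and cross-presentation, MHC class II, dendritic cell maturation, inflammatory NF-kB targets, interferon response, cholesterol synthesis, LXR and lipid handling, dead-cell uptake, NRF2 targets, glycolysis and hypoxia, the unfolded protein and ATF4 response, proliferation, ribosomal proteins, translation factors, m6A machinery, neighbours of Ythdf1, melanocyte genes and tumour stroma. Markers of macrophages, conventional and plasmacytoid dendritic cells, neutrophils, mast cells and basophils, eosinophils, B cells, T and NK cells and erythroid cells were included, as were immediate early genes, apoptosis and p53 targets, oxidative phosphorylation, pattern recognition receptors and sex chromosome genes. The 30 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. With an estimated correlation, 2 calls held over all contrasts, those of the interferon response and neutrophil lists between genotype labels without lysate.

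The genes named were Ythdf1, the 10 largest rises and falls among genes past the threshold whose libraries did not overlap between groups (leaving out predicted gene symbols), the up to 4 members of each list with the smallest p, and every measured cathepsin. Some results that fall under this rule are not reported here. For the difference of the lysate effects the non-overlap part cannot apply, and all 13 genes past the threshold are named; the 3 beyond the first 10 were chosen after their values were seen. Helz2 without lysate and Zbtb46 in both treatments fall outside the rule and were chosen likewise.

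The alternatives fixed before the data were examined were a replicate block, no filter and a filter at 6, centring on one median, quantile normalization, 3 other variance models, a fit of only the groups compared, other thresholds, an estimated correlation and rotation tests (fry) for lists, and leaving out each library in turn. With 1 library left in a group, that library is assumed to vary like the other groups. Removal of each library's trend on GC content and length, a crossed replicate block and counts without other myeloid markers were added after the data were seen. In data simulated for lysate against none in wild type over 11785 genes, the test recovered 100% of genes changed by 1 and 81% of those changed by 0.5 on the log2 scale, with 6 false calls among 191 (3.14%). The simulated errors were independent and normal, with variances from the fitted model, so this share need not hold in the real libraries.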

Results

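Gene expression was measured by RNA sequencing in mouse dendritic cells that had been grown from bone marrow with the cytokine GM-CSF. Cells came from wild-type mice and from mice labelled Ythdf1-/-. Ythdf1 is a reader protein that binds N6-methyladenosine (m6A), a chemical mark on mRNA. Each genotype was sequenced as dendritic cells alone and as dendritic cells cultured overnight with necrotic B16-OVA cells, a mouse melanoma line that carries ovalbumin, and then purified. These 4 groups held 2 libraries each, 8 in all. Any other difference in handling between cells alone and cells with lysate would be part of each lysate contrast. The table used here gave 11786 genes in log2 units and no read counts, so the depth of each library is unknown. The series also lists 4 RNA immunoprecipitation samples, 2 inputs and 2 precipitates with an antibody against YTHDF1, which were not analysed here. The stated aims were to compare transcript levels between dendritic cells of both genotypes and to find the mRNAs that Ythdf1 recognises, and only the first is addressed below. Values are log2 levels with SD, or log2 changes with the standard error of the limma fit, each from 2 libraries per group.

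Libraries separated by treatment and by genotype label. The first principal component held 49.7% of the variance and the second 27.9%, and the 2 libraries of each group lay next to each other on both. The SD of the difference between the 2 libraries of a group, over genes, was 0.14 for wild type alone, 0.14 for wild type with lysate, 0.16 for KO-labelled alone and 0.11 for KO-labelled with lysate. The third component held 8.06% of the variance and parted the libraries within both untreated groups. Gene loadings of these components, in that order, correlated with transcript GC content (Spearman rho -0.37, 0.18 and -0.61 across genes, which are not independent replicates).

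**Figure D1:**
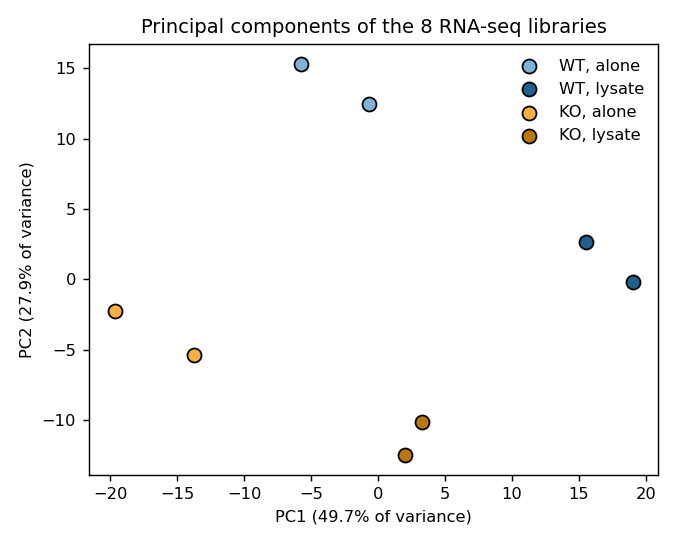
Principal components of the 8 RNA-seq libraries, with the first (49.7% of the variance) on the x axis and the second (27.9%) on the y axis, in units of the component scores. Each point is 1 library, coloured by group; libraries with lysate lie to the right of the untreated libraries of the same genotype, and KO-labelled libraries lie to the left of and below the wild-type libraries of the same treatment.

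The transcript of Ythdf1 (Entrez 228994) was not lower by the test in the libraries labelled Ythdf1-/-. Its log2 level was 9.58 and 9.43 in the wild-type libraries alone and 9.72 and 9.58 in those with lysate. It was 9.53 and 9.43 in the KO-labelled libraries alone and 9.51 and 9.46 in those with lysate. The difference between KO-labelled and wild type was -0.030 ± 0.081 without lysate (adjusted p = 0.85) and -0.16 ± 0.081 with lysate (adjusted p = 0.202). Which part of the gene is altered in these mice is not given in the sources used here, and a value for the whole gene does not check the genotype labels if the altered transcript is still made. Genotype groups are therefore named by their labels throughout, and each direction between genotypes rests on those labels.

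Wild-type dendritic cells cultured with lysate raised Ppbp, Hmox1, Cd36 and Arg1 and lowered transcripts of MHC class II. Ppbp (Entrez 57349), which encodes the chemokine CXCL7, rose 4.45-fold (log2 change 2.15 ± 0.065, adjusted p = 3.96e-10). Hmox1 (Entrez 15368), the haem-degrading enzyme haem oxygenase 1, rose 3.62-fold (1.86 ± 0.072). Cd36 (Entrez 12491), a scavenger receptor for lipids, rose 3.6-fold (1.85 ± 0.096), and Arg1 (Entrez 11846), arginase 1, rose 3.42-fold (1.78 ± 0.11). The remaining genes of the 10 with the highest rises were Dio2 (1.54), Ctsl (2.82-fold), Pdpn (1.46), Npy (1.29), Emp1 (1.26) and Rgl1 (1.26). Ctsl encodes the lysosomal protease cathepsin L and Dio2 an enzyme that activates thyroid hormone. The 10 deepest falls were Lad1 (-1.15), Hspa1b (-1.04), Sspo (-1.02), Apoa1 (-0.99), Hspa1a (-0.99), Rnase6 (-0.95), Clec12a (-0.94), Hp (-0.94), Adgre4 (-0.94) and Ly6i (-0.92). Hspa1a and Hspa1b encode near-identical heat shock proteins, so their values cannot be separated with certainty. Apoa1 lay at 4.29 and 4.17 in the untreated wild-type libraries and at 3.24 in each of the other 6, the lowest level of the table, so its value with lysate is at the floor of the scale.

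By gene group in wild type, 15 of 36 lysosome genes outside the cathepsin family rose and 0 fell (median 0.22, 18 higher and 1 lower adjusted over the list alone, adjusted p = 2.06e-06 by camera, and adjusted p = 0.101 with an estimated correlation). Among them were Atp6v0d2 (1.01), a proton pump subunit, Cd68 (0.77) and Lipa (0.59), the acid lipase. Of 12 cathepsins, 6 rose and 3 fell, with Ctsl, Ctsd (0.54), Ctsk (0.45) and Ctsb (0.44) up and Ctsf (-0.39) and Ctsc (-0.32) down (6 higher and 3 lower adjusted over the list alone, adjusted p = 0.0387 by camera, and adjusted p = 0.254 with an estimated correlation). Without wild-type lysate replicate 2 the list missed the threshold (adjusted p = 0.0513), and so did Ctsc and Ctsf. Ctsf also lost its call without wild-type alone replicate 2, and the list under quantile normalization (adjusted p = 0.151). In the oxidative stress list of NRF2 targets 10 of 22 rose and 0 fell, including Prdx1 (0.76) and Gclm (0.55) (median 0.26, 14 higher and 0 lower adjusted over the list alone, adjusted p = 2.06e-06 by camera, and adjusted p = 0.101 with an estimated correlation). In the glycolysis and hypoxia list 14 of 29 rose and 1 fell, including P4ha1 (0.68), Pgam1 (0.54) and Ldha (0.47) (15 higher and 1 lower adjusted over the list alone, adjusted p = 1.28e-05 by camera, and adjusted p = 0.101 with an estimated correlation). In the list of lipid transport and LXR targets 9 of 22 rose and 2 fell, with Fabp4 (0.94) and Lpl (0.88) beside Cd36 (9 higher and 3 lower adjusted over the list alone, adjusted p = 0.00334 by camera, and adjusted p = 0.115 with an estimated correlation). Cholesterol synthesis genes fell in 10 of 24 cases and rose in 1, with Cyp51 (-0.54) down (1 higher and 13 lower adjusted over the list alone, adjusted p = 4.18e-05 by camera, and adjusted p = 0.101 with an estimated correlation).

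MHC class II genes and their regulator fell together in wild type, with 8 of 11 lower and 0 higher (median -0.48, 0 higher and 8 lower adjusted over the list alone, adjusted p = 6.65e-06 by camera, and adjusted p = 0.214 with an estimated correlation). Ciita, the transactivator of the class II genes, fell by 0.91, H2-Eb1 by 0.60 and H2-Ab1 by 0.54 on the log2 scale. In the list for MHC class I and cross-presentation 13 of 31 fell and 2 rose, with Cybb (-0.49) and H2-K1 (-0.43) down and Calr (0.53) up (3 higher and 13 lower adjusted over the list alone, adjusted p = 0.0263 by camera, and adjusted p = 0.385 with an estimated correlation). Of 29 dendritic cell maturation genes 9 fell and 2 rose, with Icosl (-0.62) and Fscn1 (-0.54) down (3 higher and 13 lower adjusted over the list alone, adjusted p = 0.0152 by camera, and adjusted p = 0.317 with an estimated correlation). The maturation list missed the threshold without wild-type alone replicate 1 (adjusted p = 0.0736), and the class I list without wild-type alone replicate 2 (0.0645) or wild-type lysate replicate 1 (0.0557). Among interferon response genes 14 of 37 rose and 3 fell, including Rsad2 (0.81) and Ifit3 (0.60), an antiviral effector with the close copy Ifit3b (15 higher and 5 lower adjusted over the list alone, adjusted p = 0.000678 by camera, and adjusted p = 0.172 with an estimated correlation). Inflammatory NF-kB targets moved both ways, 8 of 30 up and 10 down (10 higher and 11 lower adjusted over the list alone, adjusted p = 0.681 by camera, and adjusted p = 0.688 with an estimated correlation). Those that rose included Il1rn (1.00), the interleukin 1 receptor antagonist, Cxcl3 (0.99) and Ccl2 (0.93), and those that fell included Ccl5 (-0.59).

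Transcripts of pigment cells were higher in the lysate libraries. Of 9 measured genes of the melanocyte and B16 list 7 rose and 1 fell (median 0.68, 7 higher and 1 lower adjusted over the list alone, adjusted p = 2.83e-06 by camera, and adjusted p = 0.101 with an estimated correlation). Of these 9, 4 lay above the median level of all genes in the untreated libraries, so the list does not measure pigment cell transcripts alone. Dct (Entrez 13190), a melanin synthesis enzyme, went from 4.75 ± 7.4e-05 to 5.88 ± 0.10 (SD, n = 2), and Tyrp1 from 4.75 ± 7.3e-05 to 5.79 ± 0.10. Both untreated wild-type libraries lay at nearly the same value for each gene, near the low end of the table, so these SDs do not measure the spread between cultures. Both genes lay below the library medians, which were between 8.53 and 8.55. The added cells were melanoma cells, so these transcripts were higher in the same libraries as each gene group described for lysate. Macrophage and monocyte markers moved with lysate too in wild type, 2 of 18 up and 8 down (2 higher and 8 lower adjusted over the list alone, adjusted p = 0.0224 by camera, and adjusted p = 0.317 with an estimated correlation), a call lost without wild-type lysate replicate 2 (adjusted p = 0.0513).

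**Figure D2:**
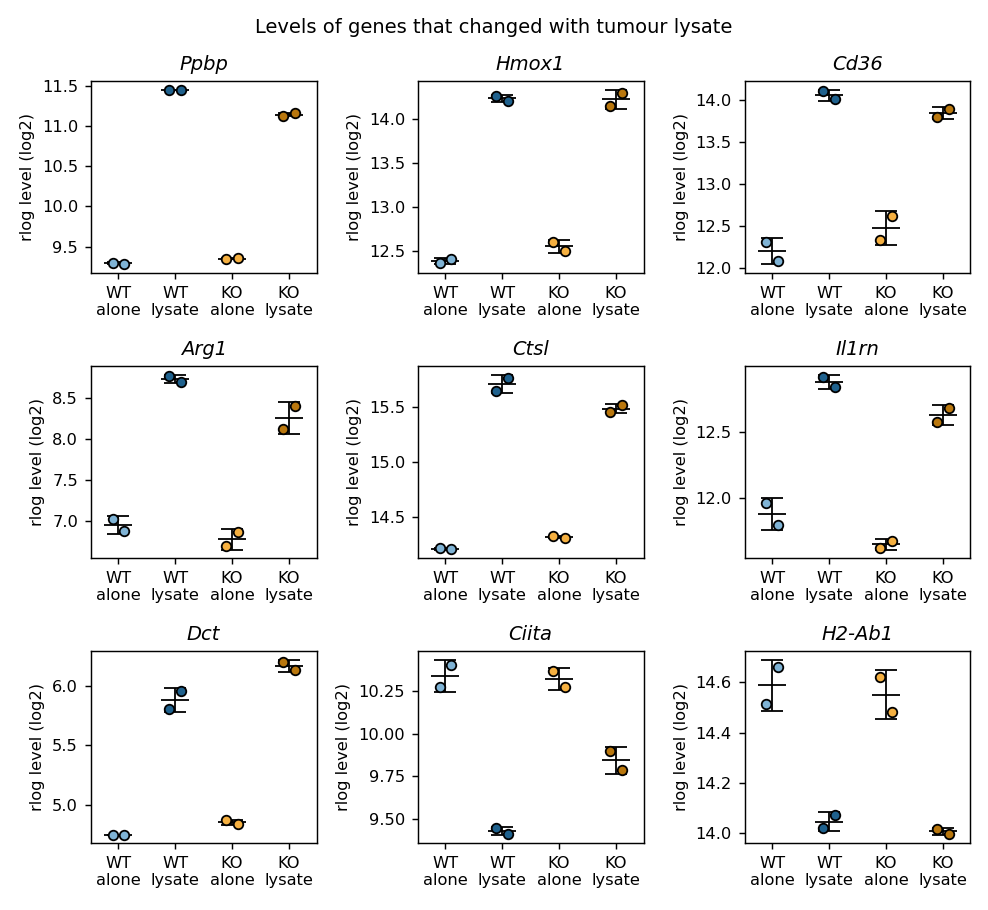
Log2 levels of 9 genes in the 4 groups, each point 1 library, with the mean and SD of the 2 libraries as bars; the y axes are cropped around each gene's values. Ppbp, Hmox1, Cd36, Arg1, Ctsl, Il1rn and Dct are higher with lysate in both genotypes, and H2-Ab1 is lower in both.

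Over all genes, 1205 rose and 1329 fell with lysate in wild type of 11785 tested (limma, Benjamini-Hochberg 0.05), 29 of them at least 2-fold. The count was 1031 without wild-type alone replicate 2 and 1110 without wild-type lysate replicate 1.

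KO-labelled dendritic cells shared 8 of the 10 highest rises with wild type, and 3 of the 10 deepest falls. Ppbp rose 3.46-fold (log2 change 1.79 ± 0.065, adjusted p = 4.49e-09), Hmox1 3.2-fold (1.68 ± 0.072) and Arg1 2.79-fold (1.48 ± 0.11). The other leading rises were Dio2 (1.44), Cd36 (1.36), Dct (1.31), Tyrp1 (1.24), Ctsl (1.17), Pdpn (1.09) and Rgl1 (1.07). The deepest falls were Lad1 (-1.14), Sspo (-1.09), Pnkd (-0.96), Clec12a (-0.91), Kcna3 (-0.86), Dscaml1 (-0.85), Scara3 (-0.79), Cdkn2c (-0.77), Reep1 (-0.77) and Nudt17 (-0.75). Clec12a encodes an inhibitory lectin receptor and Cdkn2c a cell cycle inhibitor. Kcna3 stood at 7.20 in 1 untreated KO-labelled library and at 5.89 in the other, and lost its call without the first of these (KO-labelled alone replicate 1), without either wild-type lysate library or either KO-labelled lysate library, and under 5 other alternatives, quantile normalization among them.

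By gene group, 27 of 37 interferon response genes rose in the KO-labelled cells and 1 fell (median 0.41, 28 higher and 1 lower adjusted over the list alone, adjusted p = 3.05e-16 by camera, and adjusted p = 0.0689 with an estimated correlation). Rsad2 (0.95), Ifit2 (0.94) and Ifit3 (0.86), all antiviral effectors, led them. MHC class II genes fell in 8 of 11 cases (median -0.44, 0 higher and 9 lower adjusted over the list alone, adjusted p = 4.97e-07 by camera, and adjusted p = 0.145 with an estimated correlation), with H2-Eb1 (-0.61), H2-DMa (-0.54) and Cd74 (-0.51). Lysosome genes outside the cathepsins rose in 14 of 36 cases (14 higher and 0 lower adjusted over the list alone, adjusted p = 6.03e-06 by camera, and adjusted p = 0.0905 with an estimated correlation). Of the cathepsins 4 of 12 rose and 3 fell, led by Ctsl and Ctsk (0.48), and the list missed the threshold (adjusted p = 0.0656). NRF2 targets rose in 6 of 22 cases (7 higher and 0 lower adjusted over the list alone, adjusted p = 0.000101 by camera, and adjusted p = 0.129 with an estimated correlation), glycolysis and hypoxia genes in 11 of 29 (12 higher and 1 lower adjusted over the list alone, adjusted p = 1.57e-05 by camera, and adjusted p = 0.106 with an estimated correlation) and lipid transport and LXR targets in 10 of 22, with 1 lower (11 higher and 2 lower adjusted over the list alone, adjusted p = 0.000279 by camera, and adjusted p = 0.0905 with an estimated correlation). Cholesterol synthesis genes fell in 7 of 24 cases and rose in 1, with Dhcr7 (0.49) up (1 higher and 11 lower adjusted over the list alone, adjusted p = 0.000828 by camera, and adjusted p = 0.126 with an estimated correlation). Of the 9 melanocyte genes 7 rose and 1 fell (7 higher and 1 lower adjusted over the list alone, adjusted p = 4.97e-07 by camera, and adjusted p = 0.0745 with an estimated correlation), and of 29 maturation genes 7 fell and 1 rose, including Fscn1 (-0.55) and Ccl17 (-0.53) (2 higher and 7 lower adjusted over the list alone, adjusted p = 0.0139 by camera, and adjusted p = 0.327 with an estimated correlation). The maturation list missed the threshold without KO-labelled alone replicate 2 (adjusted p = 0.0815) or KO-labelled lysate replicate 2 (0.0862). Inflammatory NF-kB targets rose in 9 of 30 cases and fell in 4, with Ccl2 (1.03) and Il1rn (0.98) up (9 higher and 4 lower adjusted over the list alone, adjusted p = 0.0138 by camera, and adjusted p = 0.129 with an estimated correlation).

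Ribosomal protein genes fell with lysate in 26 of 51 cases in the KO-labelled cells (median -0.26, 0 higher and 35 lower adjusted over the list alone, adjusted p = 5.04e-12 by camera, and adjusted p = 0.357 with an estimated correlation) and in 9 of 51 in wild type (median -0.15, 0 higher and 9 lower adjusted over the list alone, adjusted p = 0.000583 by camera, and adjusted p = 0.553 with an estimated correlation). Examples were Rps24 (-0.47) and Rpsa (-0.48) in KO-labelled and Rps14 (-0.51) in wild type. These counts moved with the libraries in the fit, and the wild-type list missed the threshold without wild-type lysate replicate 1. All groups share 1 estimate of the spread. The untreated KO-labelled libraries differed most (SD of the difference 0.16) and the KO-labelled libraries with lysate least (0.11). A lower count without 1 library can therefore be lost precision, and need not mean that the change rests on that library. In KO-labelled cells 1 fell without KO-labelled lysate replicate 1, 7 without KO-labelled lysate replicate 2 and 9 without KO-labelled alone replicate 1. In wild type 0 fell without wild-type alone replicate 2 or wild-type lysate replicate 1, 24 without wild-type lysate replicate 2, 16 without either KO-labelled alone library and 4 without either KO-labelled lysate library.

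In all, 976 genes rose and 816 fell with lysate in KO-labelled cells, 13 of them at least 2-fold. The count was 564 without KO-labelled lysate replicate 1, 567 without KO-labelled lysate replicate 2 and 1109 without KO-labelled alone replicate 1. It was 2926 after removal of the trend on GC content and length and 2919 with a crossed replicate block, both chosen after the data were seen.

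The lysate changes of both genotypes, which share no library, were correlated across the 11785 genes (Pearson r 0.75, Spearman rho 0.70, slope 0.87; genes are not independent replicates). Genes that rose in both numbered 643, where independent lists would give 99.8, and genes that fell in both numbered 489 against 92.0. Both tests take each gene's spread from the same fit of 8 libraries. Their calls can therefore overlap more than independent lists even where the changes are unrelated. Ppbp, Hmox1, Arg1, Dio2, Cd36, Ctsl, Pdpn and Rgl1 stood among the 10 highest rises in each, and Lad1, Sspo and Clec12a among the 10 deepest falls in each. There were 5 genes that passed the threshold in opposite directions. Averaged over genotypes, 1942 genes rose and 2148 fell with lysate.

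**Figure D3:**
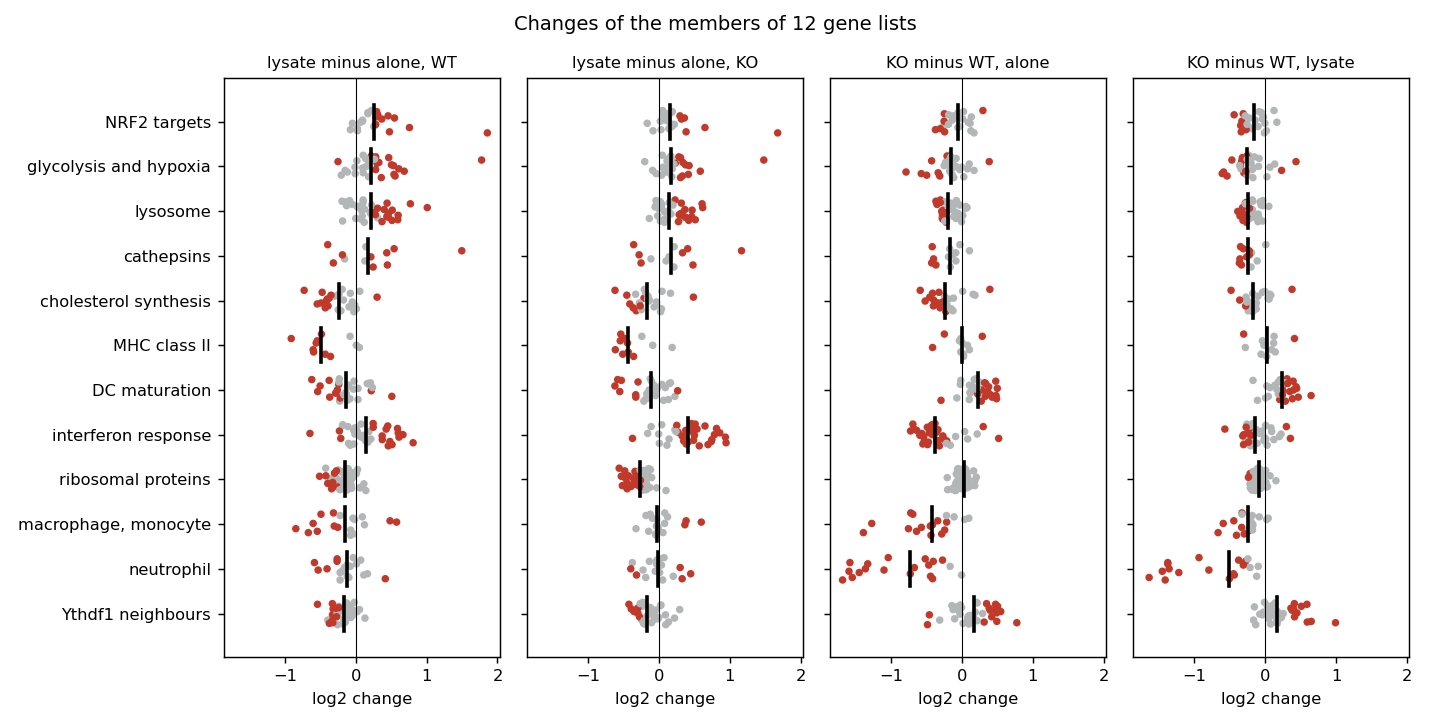
Log2 change of each measured member of 12 gene lists in 4 comparisons (panels), with members that passed the test in red, others in grey, and the list median as a black bar. The MHC class II median lies near -0.48 and -0.44 with lysate, and the neutrophil median near -0.73 and -0.50 between genotype labels.

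Dendritic cells labelled Ythdf1-/- had lower neutrophil granule and monocyte transcripts than wild type in the groups without lysate. S100a8 and S100a9 (Entrez 20201 and 20202), the calprotectin subunits abundant in neutrophils, were 3.21-fold and 3.02-fold lower (log2 change -1.68 ± 0.15 and -1.59 ± 0.10). Ngp and Camp, granule proteins, were 2.92-fold and 2.99-fold lower (-1.55 ± 0.073 and -1.58 ± 0.12, adjusted p = 1.26e-07 and 4.78e-06). The other deep falls were Stfa2 (-1.52), Hp (-1.45), Retnlg (-1.45), Cstdc5 (-1.40), Ly6c1 (-1.39) and Ltf (-1.36). Stfa2 and Cstdc5 belong to a cluster of near-identical cystatin genes, and Ly6c1 has the close copy Ly6c2, so the values of such copies cannot be separated with certainty. Higher in KO-labelled cells were Cdon (1.17), Hal (1.12), Plekhs1 (1.02), Batf3 (0.84), Adam11 (0.83), Itga3 (0.80), Npr1 (0.80), Nudt17 (0.79) and Rab26 (0.79), with the tenth an entry for a microRNA, which an mRNA library cannot part from its host transcript. Hal (Entrez 15109) encodes histidine ammonia-lyase, which was 2.17-fold higher, and Batf3 a transcription factor needed for conventional dendritic cells of type 1.

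Neutrophil markers fell in 17 of 19 cases (median -0.73, 0 higher and 17 lower adjusted over the list alone, adjusted p = 7.93e-21 by camera, and adjusted p = 0.0493 with an estimated correlation), and this was 1 of 2 lists whose call held with an estimated correlation. Macrophage and monocyte markers fell in 14 of 18 cases, including Ly6c2 (-1.27), Lyz1 (-0.72) and Cd14 (-0.64) (0 higher and 14 lower adjusted over the list alone, adjusted p = 1.73e-11 by camera, and adjusted p = 0.0714 with an estimated correlation). All 5 measured eosinophil markers fell, with the ribonuclease genes Ear2 (-0.97) and Ear1 (-0.85), which are close copies of each other (0 higher and 5 lower adjusted over the list alone, adjusted p = 1.99e-06 by camera, and adjusted p = 0.0714 with an estimated correlation). Dendritic cell maturation genes were higher. Of 29 such genes 15 rose and 1 fell, including Stat4 (0.50), Birc2 (0.49) and Socs2 (0.48) (median 0.22, 17 higher and 1 lower adjusted over the list alone, adjusted p = 1.93e-07 by camera, and adjusted p = 0.0915 with an estimated correlation). Conventional dendritic cell markers split, with 6 of 21 higher and 3 lower (9 higher and 4 lower adjusted over the list alone, adjusted p = 0.269 by camera, and adjusted p = 0.369 with an estimated correlation). Ly75 (0.51), an endocytic receptor, and Flt3 (0.41) were higher beside Batf3, and Naaa (-0.54) was lower. The maturation genes, Ly75, Flt3 and Batf3 were higher in the same libraries in which neutrophil, macrophage and eosinophil markers were lower. A changed mix of cells and a change within the cells cannot be told apart here.

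Interferon response genes fell in 29 of 37 cases and rose in 2 in the KO-labelled cells alone (median -0.38, 3 higher and 31 lower adjusted over the list alone, adjusted p = 1.03e-13 by camera, and adjusted p = 0.0493 with an estimated correlation). Examples were Irf7 (-0.73), a transcription factor of the type I interferon response, Isg20 (-0.69), Zbp1 (-0.64) and Oasl2 (-0.60). Pattern recognition receptors fell in 12 of 28 cases, including Tlr2 (-0.92) and Clec4e (-0.86) (1 higher and 16 lower adjusted over the list alone, adjusted p = 8.6e-06 by camera, and adjusted p = 0.128 with an estimated correlation). Inflammatory NF-kB targets fell in 11 of 30 cases and rose in 5, with Il1b (-0.85) and Acod1 (-0.93) down (6 higher and 13 lower adjusted over the list alone, adjusted p = 0.0322 by camera, and adjusted p = 0.128 with an estimated correlation), and this list missed the threshold without wild-type alone replicate 2 (adjusted p = 0.0639). Cathepsins fell in 4 of 12 cases and none rose (0 higher and 5 lower adjusted over the list alone, adjusted p = 0.00188 by camera, and adjusted p = 0.0979 with an estimated correlation). They were Ctss (-0.42 ± 0.069), Ctsc (-0.43 ± 0.072), Ctse (-0.40 ± 0.094) and Ctsk (-0.37 ± 0.083), of which Ctss lost its call under quantile normalization, Ctse without wild-type alone replicate 1, and Ctsk without wild-type alone replicate 2 or KO-labelled alone replicate 2. The other lysosome genes fell in 14 of 36 cases, including Man2b1 (-0.37) (0 higher and 16 lower adjusted over the list alone, adjusted p = 1.93e-05 by camera, and adjusted p = 0.0714 with an estimated correlation). MHC class II genes showed 1 higher and 2 lower of 11 (adjusted p = 0.967). The interferon, receptor, NF-kB and lysosome groups fell in the same libraries in which the neutrophil and macrophage markers were lower.

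In all, 827 genes were higher and 1088 lower in KO-labelled cells alone, 32 of them at least 2-fold. The count was 1174 without wild-type alone replicate 1, 1190 without wild-type alone replicate 2 and 1192 when only these groups entered the fit. It was 3084 after removal of the trend on GC content and length.

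**Figure D4:**
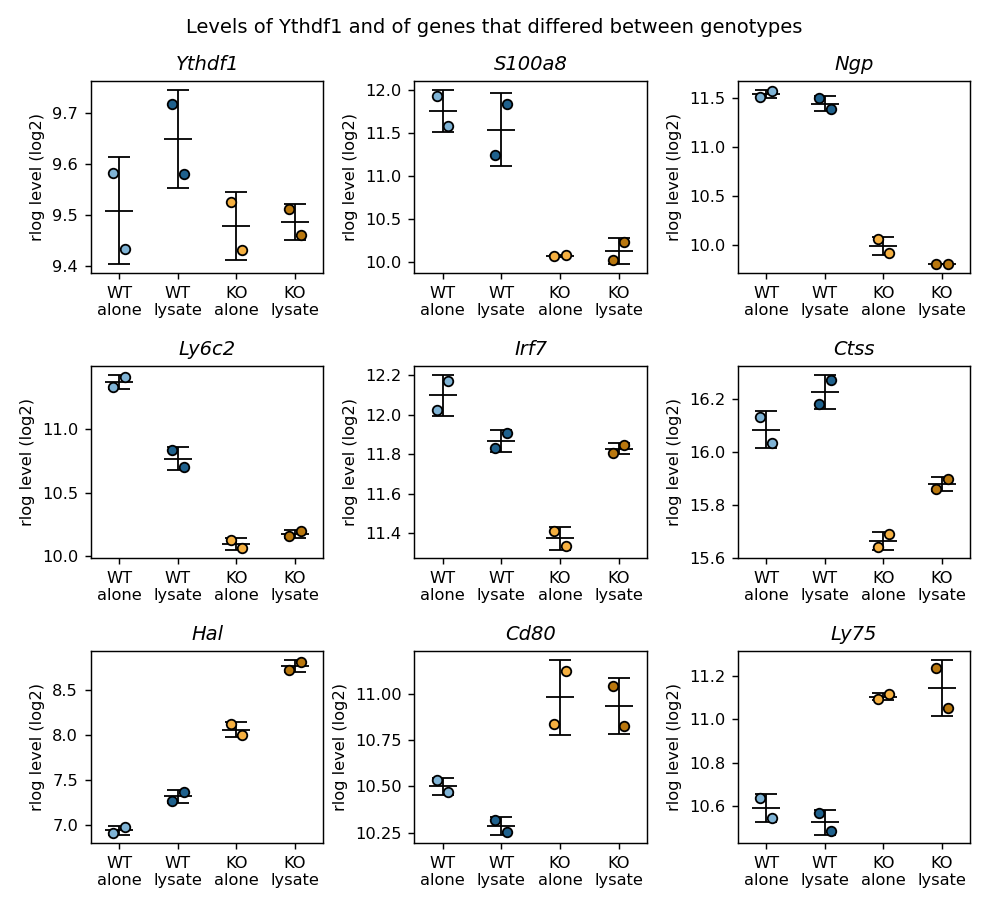
Log2 levels of 9 genes in the 4 groups, each point 1 library, with the mean and SD of the 2 libraries as bars; the y axes are cropped around each gene's values. Ythdf1 does not pass the test between genotype labels in either treatment, while S100a8, Ngp and Ly6c2 are lower and Hal, Cd80 and Ly75 higher in KO-labelled libraries of both treatments.

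With lysate, KO-labelled cells again had lower neutrophil transcripts and higher Hal. Ngp was 3.11-fold lower than in wild type (log2 change -1.64 ± 0.073, adjusted p = 6.08e-08), and S100a9 2.73-fold lower (-1.45 ± 0.10). The other deep falls were S100a8 (-1.41), Camp (-1.37), Lcn2 (-1.37), Ltf (-1.35), Retnlg (-1.22), Cd177 (-1.09), Stfa2 (-1.06) and Asprv1 (-1.02). Hal was 2.73-fold higher (1.45 ± 0.088, adjusted p = 1.11e-06). Cdon (1.00), Col20a1 (0.99), Plekhs1 (0.92), Ada (0.89), Npr1 (0.86), Cdh23 (0.82), Fgf1 (0.81), Mylk (0.80) and Tle2 (0.80) followed. Ada encodes adenosine deaminase, and Npr1 a receptor for natriuretic peptides.

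Neutrophil markers fell in 15 of 19 cases (median -0.50, 0 higher and 17 lower adjusted over the list alone, adjusted p = 2.06e-19 by camera, and adjusted p = 0.0617 with an estimated correlation), macrophage and monocyte markers in 8 of 18 (0 higher and 13 lower adjusted over the list alone, adjusted p = 3.49e-07 by camera, and adjusted p = 0.0768 with an estimated correlation) and eosinophil markers in 3 of 5 (0 higher and 3 lower adjusted over the list alone, adjusted p = 0.00017 by camera, and adjusted p = 0.0986 with an estimated correlation). Maturation genes rose in 16 of 29 cases and none fell, including Cd80 (0.65), a costimulatory ligand for T cells, and Cd83 (0.40) (median 0.24, 19 higher and 0 lower adjusted over the list alone, adjusted p = 4.1e-08 by camera, and adjusted p = 0.0768 with an estimated correlation). Of 21 conventional dendritic cell markers 6 rose and 3 fell, with Ly75 (0.62), Irf8 (0.45) and Irf4 (0.45) higher and Naaa (-0.55) lower (7 higher and 6 lower adjusted over the list alone, adjusted p = 0.158 by camera, and adjusted p = 0.266 with an estimated correlation). Il12b (0.60), a subunit of interleukin 12, was higher within an NF-kB list that moved both ways, 8 up and 7 down of 30 (9 higher and 8 lower adjusted over the list alone, adjusted p = 0.882 by camera, and adjusted p = 0.872 with an estimated correlation). Cathepsins fell in 8 of 12 cases (median -0.24, 0 higher and 10 lower adjusted over the list alone, adjusted p = 2.05e-05 by camera, and adjusted p = 0.0768 with an estimated correlation). They were Ctsc (-0.36), Ctse (-0.36), Ctss (-0.35), Ctsk (-0.33), Ctsd (-0.31), Ctsz (-0.26), Ctsl (-0.22) and Ctsh (-0.22). Under quantile normalization Ctss, Ctsd and Ctsl lost their calls. The values of the other cathepsins were Ctsa (-0.20), Ctsb (-0.19), Ctso (-0.11) and Ctsf (0.0093). Lysosome genes outside this family fell in 15 of 36 cases, including Atp6ap1 (-0.35) (0 higher and 25 lower adjusted over the list alone, adjusted p = 8.1e-09 by camera, and adjusted p = 0.0617 with an estimated correlation). Interferon response genes fell in 9 of 37 cases and rose in 2, with Cxcl10 (-0.57) down and Mx1 (0.36) up (4 higher and 17 lower adjusted over the list alone, adjusted p = 0.00413 by camera, and adjusted p = 0.161 with an estimated correlation). Glycolysis and hypoxia genes fell in 11 of 29 cases and rose in 2, with Aldoc (-0.61) and Slc2a3 (-0.59) down (2 higher and 16 lower adjusted over the list alone, adjusted p = 3.98e-06 by camera, and adjusted p = 0.0768 with an estimated correlation). MHC class II genes showed 1 higher, Ciita (0.41), and 1 lower of 11 (adjusted p = 0.707).

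In all, 877 genes were higher and 642 lower in KO-labelled cells with lysate, 13 of them at least 2-fold. All groups share 1 estimate of the spread, and the 2 KO-labelled lysate libraries differed least (SD of the difference 0.11). Leaving 1 of them out therefore also costs precision, and calls lost in that way need not be lost changes. Among the libraries left out in turn, KO-labelled lysate replicate 1 moved this count most. Without it 193 genes differed, 0 cathepsins, 0 other lysosome genes and 0 interferon genes were lower, 1 maturation gene was higher, and 9 neutrophil markers were lower. The calls of Cd83, Irf8, Irf4, Ciita, Mx1, Cxcl10 and Atp6ap1 were lost without this library as well. The neutrophil and macrophage markers were lower in the same libraries in which the lysosome, interferon and glycolysis groups were lower. The maturation genes were higher in these libraries too. The count of genes was 488 without KO-labelled lysate replicate 2, 670 without wild-type lysate replicate 1 and 716 without wild-type lysate replicate 2. It was 2545 after removal of the trend on GC content and length and 2638 with a crossed replicate block.

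Genotype differences with and without lysate, which share no library, were correlated across genes (Pearson r 0.71, Spearman rho 0.64, slope 0.87). Higher in both were 505 genes against 61.5 for independent lists, and lower in both 419 against 59.3, with 1 gene in opposite directions. Here too the tests share each gene's spread, so independent lists can be too low a baseline. Hal, Cdon, Plekhs1 and Npr1 stood among the 10 highest rises in each, and S100a8, S100a9, Camp, Ngp, Stfa2, Retnlg and Ltf among the 10 deepest falls in each. Averaged over treatment, 1611 genes were higher and 1613 lower, 3224 in all, and 1973 differed without KO-labelled lysate replicate 1.

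Several genes close to Ythdf1 on its chromosome were higher in the KO-labelled libraries. The order of genes was taken from the GRCm38.p6 annotation. Of 35 measured neighbours 12 rose and 2 fell without lysate (median 0.16, 15 higher and 2 lower adjusted over the list alone, adjusted p = 0.00035 by camera, and adjusted p = 0.303 with an estimated correlation). With lysate 11 rose and 0 fell (median 0.16, 11 higher and 0 lower adjusted over the list alone, adjusted p = 2.95e-06 by camera, and adjusted p = 0.224 with an estimated correlation). After removal of the trend on GC content and length the medians were 0.16 without lysate and 0.083 with it. Col20a1, a collagen gene and the next but 1 measured gene from Ythdf1, was higher by 0.77 ± 0.079 alone and 0.99 ± 0.079 with lysate. Srms was higher by 0.47 ± 0.080 and 0.59 ± 0.080, and Helz2 by 0.31 and 0.59. The dendritic cell transcription factor Zbtb46 lies among these genes, with differences of 0.42 and 0.41. With lysate against none, the same list fell in 10 of 35 cases in wild type (0 higher and 12 lower adjusted over the list alone, adjusted p = 4.32e-05 by camera, and adjusted p = 0.317 with an estimated correlation) and in 7 of 35 in KO-labelled cells (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.000754 by camera, and adjusted p = 0.357 with an estimated correlation).

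**Figure D5:**
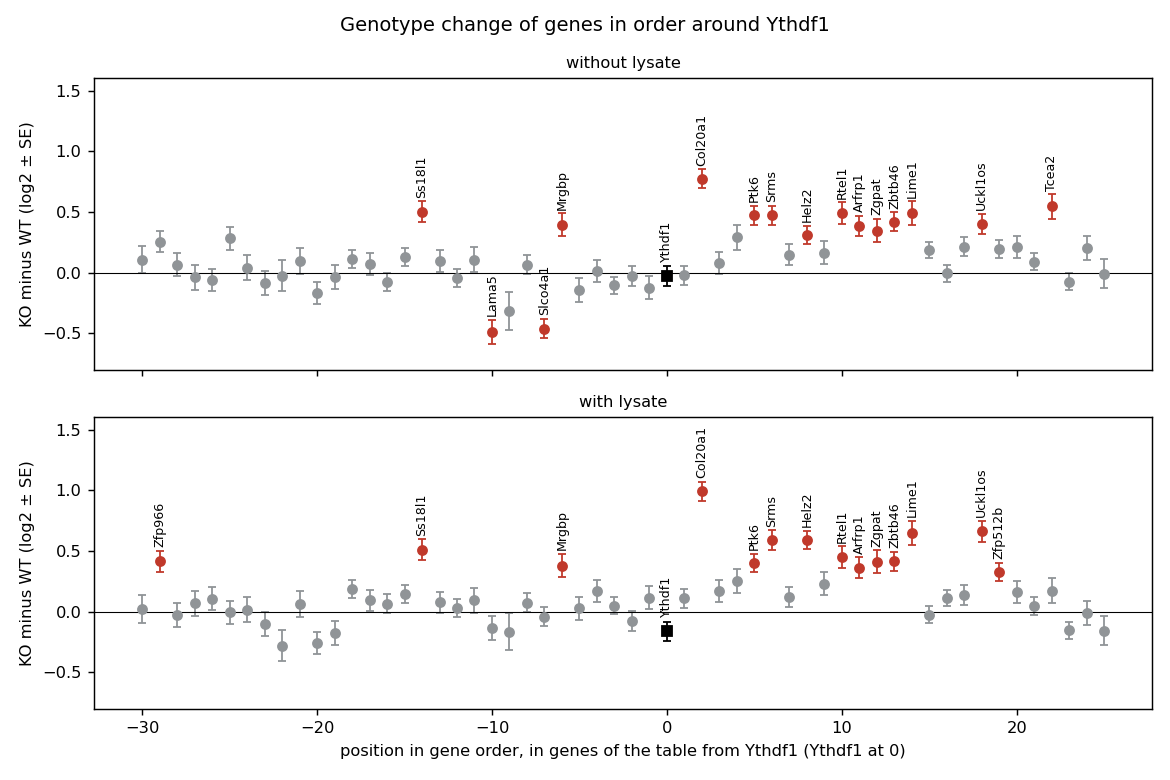
Log2 difference between KO-labelled and wild-type libraries, with its standard error, for genes of the table in their order along the chromosome around Ythdf1 (black square, at 0), without lysate above and with lysate below. Genes that passed the test are red and named; Col20a1, at 0.77 and 0.99, stands highest, and most of the red points lie on 1 side of Ythdf1.

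The effect of lysate differed between genotype labels for 13 genes, all with a higher lysate effect in KO-labelled cells, and 980 genes had an unadjusted p under 0.05 in this limma test. They were Hspa1b (1.13), Hspa1a (1.05), Apoa1 (0.99), Ly6i (0.80), Hp (0.76), Ly6c1 (0.73), Siglec1 (0.71), Irf7 (0.68), Ly6c2 (0.68), C3 (0.67), Trem1 (0.67), Slfn4 (0.64) and Cfb (0.61). A higher effect need not be a rise in KO-labelled cells. Hspa1b, Hspa1a, Apoa1, Ly6i and Hp were among the 10 deepest falls with lysate in wild type, and none was among those in KO-labelled cells. Irf7 had an adjusted p of 0.026 and a standard error of 0.10. It went from 12.10 ± 0.10 to 11.87 ± 0.056 in wild type and from 11.37 ± 0.056 to 11.83 ± 0.028 in KO-labelled cells. C3 and Cfb encode complement factors, and Hp haptoglobin. The interferon response list had a median difference of 0.22 (14 higher and 0 lower adjusted over the list alone, adjusted p = 7.47e-13 by camera, and adjusted p = 0.107 with an estimated correlation), with 1 of 37 members past the threshold. The count of 13 genes became 0 without wild-type lysate replicate 1, KO-labelled lysate replicate 1 or KO-labelled lysate replicate 2. It became 2 without wild-type alone replicate 1 or wild-type lysate replicate 2, 4 without wild-type alone replicate 2 and 32 without KO-labelled alone replicate 1. With other settings it was 1 with a replicate block or without the mean-variance trend, 8 with the filter at 6 and 21 at an adjusted p under 0.10. It was 54 with a crossed replicate block and 101 after removal of the GC and length trend, both chosen after the data were seen. Of the 13, none kept its call under every alternative run.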

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

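Tests of explanations in this part were chosen after the result was seen, and removal of the trend on GC content and length after the data were seen. The bound on the neighbours' change in the test of GC content and length was set before that test was run.

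The difference of the lysate effects between genotype labels was tested itself, as an interaction, and 13 genes passed, each with a higher lysate effect in KO-labelled cells. Their log2 differences were Hspa1b 1.13, Hspa1a 1.05, Apoa1 0.99, Ly6i 0.80, Hp 0.76, Ly6c1 0.73, Siglec1 0.71, Irf7 0.68, Ly6c2 0.68, C3 0.67, Trem1 0.67, Slfn4 0.64 and Cfb 0.61. Left-out libraries moved the count of 13 to between 0 (wild-type lysate replicate 1, or either KO-labelled lysate library) and 32 (KO-labelled alone replicate 1). Apoa1 is at the floor of the scale in 6 of the 8 libraries. A higher effect in KO-labelled cells can be the lack of a wild-type fall, since Hspa1b, Hspa1a, Apoa1, Ly6i and Hp fell with lysate in wild type.

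By camera, 10 lists differed between genotype labels in their lysate effect, and none of the 10 did with an estimated correlation. Median differences above 0 were those of the interferon response (0.22), eosinophil (0.18), macrophage (0.15), neutrophil (0.14), immediate early (0.12), inflammatory NF-kB (0.11) and pattern receptor lists (0.11). Those below 0 were the translation factors (-0.11), ribosomal proteins (-0.10) and NRF2 targets (-0.090). The ribosomal list had an adjusted p of 0.852 without wild-type lysate replicate 2 and of 0.103 without KO-labelled alone replicate 1. The translation factor list lost its call without wild-type lysate replicate 2 (0.0881). The NRF2 list lost its call without wild-type alone replicate 1 (0.106), wild-type lysate replicate 2 (0.0568), KO-labelled alone replicate 1 (0.124) or KO-labelled lysate replicate 1 (0.143). The neutrophil list lost it without wild-type alone replicate 1 (0.0836), wild-type lysate replicate 1 (0.121), KO-labelled alone replicate 2 (0.191) or KO-labelled lysate replicate 2 (0.166). The eosinophil list lost it without wild-type lysate replicate 1 (0.147) or KO-labelled lysate replicate 1 (0.0507), and the pattern receptor list without wild-type alone replicate 1 (0.13), wild-type lysate replicate 2 (0.159) or KO-labelled alone replicate 1 (0.09).

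Neutrophil and interferon genes were lower in the KO-labelled libraries without lysate. Under quantile normalization the neutrophil median stayed at -0.73 without lysate and -0.48 with it, against -0.73 and -0.50 before. The interferon median without lysate stayed at -0.38 (standard error 0.030), against -0.38 before. These values decide little on scaling between libraries. The library medians already lay between 8.53 and 8.55, so quantile normalization had little to move around the middle of the scale. At the top of the scale the highest values of the libraries ran from 17.51 to 17.88. Ctss, Ctsb and Gpnmb, at high levels, changed sign under quantile normalization in averaged contrasts. A smaller share of neutrophils in the KO-labelled cultures may be the source of the neutrophil fall, which was -0.50 with lysate too. The labels say that dendritic cells were purified, by a method not given in the sources used here, and no cell counts were used, so this and a change within the cells cannot be told apart. Fewer neutrophils, macrophages and monocytes, or eosinophils stay open as the source of the interferon fall too. By list means, the interferon list recovered with lysate by 69.1%, and the neutrophil list by 13.3%, the macrophage and monocyte list by 44.6% and the eosinophil list by 33.3%. The neutrophil mean was -0.88 without lysate and -0.77 with it, a smaller recovery than that of the medians above. Beyond these shares the interferon recovery was 0.187 (standard error 0.0396), 0.0819 (0.0221) and 0.12 (0.0584). This decides nothing, because it takes the interferon level per cell as fixed, and lysate raised the interferon list in both genotypes (median 0.14 and 0.41). A genotype effect on interferon genes stays open as a hypothesis, and rests on labels that the Ythdf1 transcript level does not check.

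The list of genes next to Ythdf1 was higher in the KO-labelled libraries. Co-movement as a usual feature of neighbouring genes is argued against, since 0.345% of 11014 runs of 35 consecutive genes elsewhere had a mean change as large in size (0.18 for the list). Those 38 runs were all falls, on 2 chromosomes, down to -0.25, while the highest rise elsewhere was 0.14, so co-movement of this size does occur in places. The runs overlap, each starting at the next gene, so they are not separate trials. The list itself leaves out some measured genes within its span. GC content and length as the whole cause are argued against as well, since after removal of those trends the median was at least 3.09 standard errors above 0 (larger adjusted p = 0.00124). As part of the cause they stay open, because the median with lysate was then 0.083 against a bound of 0.082. This bound, the share of its size that the median had to keep, was set before the test was run. The margin lies within the standard error of 0.027, and the demand that it exceed that error was added after the value was seen. A strain variant or the engineered allele acting in the region is a candidate explanation, with 11 members higher in both treatments and 0 in opposite directions, but it is confounded with the genotype labels and cannot be told apart from an effect of the genotype.

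Genes were higher in the libraries with lysate, melanocyte genes among them. RNA of the added tumour cells stays open as the source of the melanocyte rise. The increments of Pmel, Tyrp1, Dct and Slc45a2 had log2 ratios between genotypes of 0.33, 0.55, 0.42, 0.27, a range of 0.28. This decides nothing, since a response of the dendritic cells could give like ratios, and the untreated levels of these genes, down to 3.63, are low enough to be shrunk. For the other genes that rose the question stays open as well, because their ratio lay outside that of the melanocyte genes in 3 of 4 pairs of libraries, with a smallest gap of 0.37. Of 1935 such genes, 1443 had increments above the highest of the melanocyte genes, 37.4 on the unlogged scale. Tumour RNA alone could give this only if the added cells held more of each such transcript than of the melanocyte ones, which was not measured. The melanocyte increments may also be understated, since low levels are shrunk. These points concern rises only. Added RNA is no direct source of a fall, and 1329 genes fell with lysate in wild type and 816 in KO-labelled cells. It could lower other transcripts only as a share of the reads, and the share of tumour RNA was not measured. A response of the dendritic cells to lysate stays open as a hypothesis.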

How the results depend on the processing

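The alternatives that removed the trend on GC content and length, crossed the replicate block and left out other myeloid markers were chosen after the data were seen, and all others before.

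The Ythdf1 difference stayed short of the threshold under all alternatives run. Without single libraries it was -0.10 to 0.044 without lysate and -0.23 to -0.095 with it. The correlation of the lysate effects was 0.652 to 0.751 without single libraries and 0.845 over genes past the threshold in either contrast. That of the genotype effects was 0.628 to 0.725 and 0.858. Counts of changed genes without single libraries were 1031 to 3154 for lysate in wild type, 564 to 2275 for lysate in KO-labelled, 1174 to 1865 for genotype alone and 193 to 2057 for genotype with lysate. They were 0 to 32 for the interaction, 2780 to 4620 for lysate averaged and 1973 to 3469 for genotype averaged. Called lists were, in the same order, 12 to 17, 12 to 18, 15 to 20, 16 to 19, 7 to 13, 12 to 16 and 16 to 21. A design of 2 libraries per group and an unknown depth limit all of these.

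A change of at least 2-fold besides the adjusted p left, in that order, 29, 13, 32, 13, 2, 19 and 20 genes, by construction. An adjusted p under 0.10 gave 2427 genes for genotype with lysate and 21 for the interaction. A fit of only the groups compared gave 1192 for genotype alone, with 2 residual degrees of freedom. The interaction count was 8 with the filter at 6, 1 without the mean-variance trend, and its cause was not tested. After removal of the GC and length trend 2926 genes changed with lysate in KO-labelled, 3084 between genotypes alone, 2545 with lysate and 101 (84 higher) in the interaction; of the main calls 1713, 1853, 1374 and 13 were among them, and the cause was not tested. With an estimated correlation 0, 0, 2, 0, 0, 0 and 0 lists were called. The rotation test fry called 3 lists for the interaction and 22 for lysate averaged by direction. Mixed, it called 29 and 28 for lysate in wild type and KO-labelled, 6 for the interaction and 30 for lysate averaged, which asks another question than camera does. The filter removes 1 gene, so leaving it out says little. The neutrophil, macrophage, eosinophil and mast cell lists hold 19, 18, 5 and 6 genes, so leaving them out could hardly move a count and says nothing on their part in it.

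The replicate block left 1994, 1407, 1540, 1086, 1, 3591 and 2803 genes, in the same order. Replicate differences of the groups correlated by 0.26, -0.61, 0.091, -0.27, 0.099 and -0.048, so the numbers do not pair the samples. A crossed replicate block gave 2919 genes for lysate in KO-labelled, 2638 for genotype with lysate and 54 for the interaction (47 higher).

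Under quantile normalization 3 named genes changed sign, each by the averaged contrasts, Ctss with lysate (-0.023), Ctsb (0.014) and Gpnmb (0.020) between genotypes, and the cause was not tested. Among all results for named genes 24 others lost and 4 gained a call there, and 7 list calls were lost. No count model (DESeq2) was run, since no counts were used here, and nothing was computed for the immunoprecipitation samples, which have no column.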

Other observations

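The tests of other splits of the libraries were set before the data were examined, and the count of balanced splits was added after.

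With lysate, single genes of protein folding, dead-cell uptake and cell division rose. The unfolded protein and ATF4 list in wild type had 9 higher and 3 lower of 24 (9 higher and 3 lower adjusted over the list alone, adjusted p = 0.0224 by camera, and adjusted p = 0.317 with an estimated correlation), led by the chaperone genes Pdia4 (0.81) and Hspa5 (0.49), and lost its call without wild-type alone replicate 1 (adjusted p = 0.0894) or wild-type lysate replicate 2 (0.0533). Translation factors had 11 higher and 3 lower of 35 (11 higher and 5 lower adjusted over the list alone, adjusted p = 0.0456 by camera, and adjusted p = 0.317 with an estimated correlation), with Eif4e (0.70), the cap-binding factor, and the list lost its call without either wild-type alone library (0.056 and 0.0602), wild-type lysate replicate 2 (0.289) or either KO-labelled lysate library (0.052 for each). Dead-cell uptake genes had 6 higher and 2 lower of 24 (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.0764 by camera, and adjusted p = 0.317 with an estimated correlation), with the scavenger receptor genes Msr1 (0.85) and Mrc1 (0.86). Proliferation genes had 5 higher and 3 lower of 37 (6 higher and 3 lower adjusted over the list alone, adjusted p = 0.144 by camera, and adjusted p = 0.317 with an estimated correlation), with Ccnd1 (0.98), cyclin D1, and Pcna (0.86). Of the m6A machinery 1 of 21 genes rose, Igf2bp2 (1.08), a reader of m6A (1 higher and 0 lower adjusted over the list alone, adjusted p = 0.361 by camera, and adjusted p = 0.688 with an estimated correlation). In KO-labelled cells pattern recognition receptors had 13 higher and 2 lower of 28 (14 higher and 3 lower adjusted over the list alone, adjusted p = 0.00066 by camera, and adjusted p = 0.281 with an estimated correlation), with Tlr13 (0.54) and Tlr7 (0.54).

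Between genotype labels without lysate, cholesterol synthesis genes had 1 higher and 12 lower of 24 (1 higher and 12 lower adjusted over the list alone, adjusted p = 2.03e-05 by camera, and adjusted p = 0.0714 with an estimated correlation), with Fdps (-0.52). Proliferation genes had 3 higher and 7 lower of 37 (3 higher and 7 lower adjusted over the list alone, adjusted p = 0.0199 by camera, and adjusted p = 0.102 with an estimated correlation), with the division genes Cenpf (-0.70) and Mki67 (-0.62). Apoptosis and p53 targets had 6 higher and 1 lower of 23 (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.00233 by camera, and adjusted p = 0.0915 with an estimated correlation), with Pmaip1 (0.53), and immediate early genes 2 higher and 12 lower of 27 (3 higher and 12 lower adjusted over the list alone, adjusted p = 0.000695 by camera, and adjusted p = 0.29 with an estimated correlation), with Klf2 (-0.73). Tumour stroma genes had 1 higher and 5 lower of 13 (2 higher and 6 lower adjusted over the list alone, adjusted p = 0.00609 by camera, and adjusted p = 0.139 with an estimated correlation), with Fn1 (-0.50). Oxidative phosphorylation genes with lysate had 0 higher and 5 lower of 30 (0 higher and 5 lower adjusted over the list alone, adjusted p = 0.000283 by camera, and adjusted p = 0.389 with an estimated correlation), a call lost without wild-type lysate replicate 2 (0.131). The m6A machinery had 0 higher and 0 lower of 21 (0 higher and 0 lower adjusted over the list alone, adjusted p = 0.611 by camera, and adjusted p = 0.901 with an estimated correlation) without lysate. Plasmacytoid dendritic cell markers had 0 higher and 2 lower of 10 (0 higher and 2 lower adjusted over the list alone, adjusted p = 0.585 by camera, and adjusted p = 0.61 with an estimated correlation) and mast cell and basophil markers 0 higher and 2 lower of 6 (2 higher and 2 lower adjusted over the list alone, adjusted p = 0.174 by camera, and adjusted p = 0.369 with an estimated correlation). The B cell list had 3 measured members and 0 called without lysate, the T and NK cell list 1 higher and 1 lower of 4, the erythroid list 1 higher of 2, and the sex chromosome list 0 of 4, with none of these tested as a list. The neutrophil and macrophage markers were lower in the same KO-labelled libraries.

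A list's median, mean and test differed in sign for eosinophil markers with lysate in wild type, and for proliferation, m6A, stroma, macrophage and plasmacytoid lists in KO-labelled. Between genotypes they differed for MHC class II, ATF4 and translation factor lists without lysate, for immediate early genes with lysate and for MHC class II averaged. For the interaction they differed for MHC class II, maturation, dead-cell uptake and conventional dendritic cell lists. None of these lists was called in those contrasts.

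With the other factor as a term, 3975 genes differed by lysate and 3124 by genotype label, and 1 of 34 splits of the 8 libraries, the real one, gave as many in each case. The highest other split gave 0 genes by limma in both, with up to 2623 and 1879 genes at an unadjusted p under 0.05. The real factor was no term in the fits of the other splits. Its differences stayed, at least in part, in their spread and held calls down, so 0 calls there say little. A share under 0.05 had been set as the bound, but 16 of the 34 splits hold unequal numbers of libraries of each level of the other factor, so those are no fair exchange of libraries. The splits balanced over that factor number 18, too few for a share under 0.05, and the highest other of them gave 0 and 0 genes by limma, with up to 1349 and 1879 at an unadjusted p under 0.05. The 2 libraries of a group may come from 1 culture, and differences between cultures were not tested by either count.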
